A study of Homo sapiens with 12 samples.

How the data were processed

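RNA-seq libraries from 12 human cell samples in 4 groups of 3 were analysed. Both transplanted groups held microglia made from the human embryonic stem cell line H1 (WA01). These had been transplanted into mouse brain after PLX5622, an inhibitor of the CSF1 receptor, and were later taken back from it. Both groups carried the tags 0wk and 2wk, which the labels do not explain. The primary group held microglia from human brain tissue. The progenitor group held CD14+ cells differentiated from H1 in vitro. Per the labels' protocols, live human CD45+ CD11b+ cells were sorted and libraries were made with a kit that amplifies full-length cDNA from few cells (SMART-Seq v4). Groups and replicate numbers were taken from the sample titles. The transplanted 2wk group carried the replicate numbers 1, 2 and 4.

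The deposited table gave 1 normalized read count per gene and library, a signal that is never negative, and the authors' scaling had divided each library by 1 factor. The submitters' processing notes name bcl2fastq, STAR 2.5.2b, HTSeq, RSEM and DESeq2 3.17, and the genome builds mm10, GRCm38.p6 and hg38, without saying which tool or build gave the table. How human reads were separated from mouse reads, whether strand was used in counting, and which filter chose the genes are not given in the sources used here. The table held 13875 genes by symbol, of which 13865 were matched to GENCODE release 29 on GRCh38 and 13851 were annotated as protein coding. Genes of the Y chromosome (9) were left out of every step, which left 13866 genes. Of these, 119 were at 0 in every library.

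The values of each library were whole multiples of 1 step, so the reads behind them could be recovered: 100% of the values above 0 came out whole within a tolerance of 0.1 reads. Recovered depth ran from 10 to 36.2 M reads per library. The step of transplanted 0wk replicate 3 was too close to 1 to be told from rounding, so this library was left out of the count models, which ran on 11 libraries. Intervals and lower bounds given for genes with few reads in a group cover counting error only, and neither the spread between libraries nor copies made by amplification, since the reads carried no molecular identifiers. Where every library of a group was at 0, the fold was computed against a floor of 3 reads per library and is printed as "at least". Where a group held 1 to 30 reads in total, the ratio of the group means is printed with its 95% counting interval.

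Genes with at least 10 normalized reads in at least 3 libraries (12268) were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(normalized read count + 1). A single fit held all 12 libraries and 4 group means, and the comparisons were contrasts of these means. The transplanted mean gave both transplanted groups equal weight. Fold changes are therefore on the log2(value + 1) scale, which understates changes of genes with few reads. P-values were adjusted by the Benjamini-Hochberg method, a gene was called changed at an adjusted p under 0.05, and errors of fold changes are standard errors. Gene lists (30) were written from general knowledge of microglia and of other brain and blood cells before the data were examined. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists within a comparison. The distance of each library to the mean primary profile was Euclidean over the genes tested, with each primary library set against the mean of the other primary libraries. The overlap between comparisons that share the progenitor libraries was set beside simulated unchanged groups and beside the overlap of independent lists.

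The genes named were fixed by a rule written before the data were examined. They are the 10 higher and 10 lower genes of each comparison with the largest change among those called, with a mean of at least 100 normalized reads in the higher group and no overlap between the groups. To these were added 10 markers whatever their result, and at most 2 higher and 2 lower members of each list by adjusted p. Genes that differ between people by deletion or copy number, classical HLA genes and uncharacterised loci were not named for their size.

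The tests were checked on simulated reads drawn from the real means and depths, with 200 changed genes. The changed genes were taken only from the more abundant ones, so the shares recovered do not cover genes with few reads. Noise was independent between genes and libraries, without the close pairs of the real data, so the shares of false calls hold only for such noise. For transplanted against progenitor cells (11638 genes), 47.8% of the 2-fold, 91.0% of the 4-fold and 98.5% of the 8-fold changes were recovered, and 7.60% of the calls were false. For the 2wk against the 0wk group (11637 genes), the shares recovered were 43.3%, 85.1% and 97.0%, and 2.60% of the calls were false. For transplanted against primary cells (11635 genes) they were 46.3%, 94.0% and 100%, with 5.33% false calls, and for primary against progenitor cells (11625 genes) 20.9%, 88.1% and 98.5%, with 6.76% false calls. Alternatives covered the pseudocount, the filter, the scaling, the libraries in the fit, library weights, the replicate number as a block, each library left out, the threshold, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and each transplanted group alone. Averaging the closest libraries and removing trends with GC content and transcript length were added after the data had been seen. Averaging leaves fewer samples in the fit, so a call can be lost without a smaller change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.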

Results

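Gene expression was measured by RNA-seq in 12 libraries of human cells: 3 of transplanted microglia tagged 0wk, 3 of transplanted microglia tagged 2wk, 3 of primary microglia from human brain and 3 of CD14+ progenitors in culture. The transplanted cells and the progenitors came from the same stem cell line, H1. The recovered depth was 10 to 20.4 M reads in the 0wk libraries and 15.7 to 23.9 M in the 2wk libraries. It was 10.4 to 18.2 M in the primary libraries and 25 to 36.2 M in the progenitor libraries. SPP1, which encodes the secreted phosphoprotein osteopontin, was the most abundant transcript in every transplanted library, with 3.68% to 6.12% of the normalized reads. FOS, an immediate early transcription factor, led in every primary library (1.88% to 3.09%), and FTL, the ferritin light chain, in every progenitor library (5.11% to 5.54%).

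Libraries of a group differed by more than sampling noise in every pair, with a chi-square per gene between 3.81 and 207. In every group 1 pair was far closer than the others, at 21 against 103 and 125 for 0wk, 9.68 against 89.6 and 94.4 for 2wk, 3.81 against 180 and 207 for primary and 8.40 against 40.3 and 52.6 for progenitor libraries. Ribosomal protein transcripts took 2.89% ± 0.203 (SD, n = 3) of the normalized reads in the 2wk libraries and 1.21% ± 0.15 in the 0wk libraries, against 1.31% ± 0.988 (0.73% to 2.45%) in primary and 1.79% ± 0.168 in progenitor libraries. Mitochondrially encoded transcripts took 1.39% ± 0.0451, 0.78% ± 0.188, 1.12% ± 0.951 and 2.65% ± 0.0742 of the reads in the same order. The labels number the donors of the primary libraries, but 1 pair of these was far closer than the others (3.81 against 180 and 207). Independent replicates are therefore not certain there. That chi-square was the lowest in the series, but the measure also grows with depth. By rank, progenitor replicates 1 and 2 were closer (Spearman's rho of 0.9958 against 0.9943 for the primary pair). For the other groups the labels do not say whether replicates came from separate cultures or animals. P-values and SDs therefore measure only the spread between these libraries, and n counts libraries.

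The series concerns CSF1 receptor signalling and how human microglia integrate into the mouse brain, and the first question the groups allow is what distinguished the transplanted cells from the progenitors. Microglial genes stood far higher after transplantation. CX3CR1, the fractalkine receptor (ENSG00000168329.13, GRCh38 chromosome 3, 39263494 to 39281735), was at 111500 ± 23900 normalized reads (SD, n = 6) in transplanted cells and 58.7 ± 18.6 (n = 3) in progenitors, a log2 fold change of 10.88 ± 0.25 (limma, adjusted p = 9.43e-12). SALL1, a transcription factor of microglia (chromosome 16, 51135975 to 51151367), was at 1710 ± 375 and was not detected in progenitors, at least 935-fold higher. The purinergic receptor gene P2RY12 (chromosome 3, 151337380 to 151384812) rose by 7.23 ± 0.35 log2 units and the microglial surface marker TMEM119 (chromosome 12, 108589846 to 108598320) by 5.90 ± 0.31. FCN1, which encodes the monocyte lectin ficolin-1, was at 2737 ± 521 in progenitors and not detected in transplanted cells, at least 786-fold lower.

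Of the 23 measured homeostatic microglia genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 3.19. The homeostatic list had an adjusted p of 2.73e-15 by camera, and adjusted p = 0.0297 with an estimated correlation. SYNDIG1, which encodes a synapse-associated membrane protein, was at least 680-fold higher. All 21 measured cholesterol synthesis genes fell, also when adjusted over the list alone, with a median of -3.80. By camera, the cholesterol synthesis list had an adjusted p of 4.13e-17, and adjusted p = 0.00434 with an estimated correlation. INSIG1, which holds back sterol sensing, fell by 6.32 ± 0.18 log2 units and FDFT1, squalene synthase, by 4.11 ± 0.14. Of 21 monocyte and early myeloid genes, 17 fell and 2 rose (17 and 3 adjusted over the list alone), with a median of -3.05, or -2.80 with genes at 0 set to their bound. For the monocyte list, camera gave an adjusted p of 2.83e-07, and adjusted p = 0.0445 with an estimated correlation. S100A8, a calcium-binding alarmin, fell by 5.57 ± 0.28 log2 units, while CSF3R, the receptor of a granulocyte growth factor, rose by 0.85 ± 0.26.

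Immediate early and dissociation genes were mostly higher in transplanted cells, with 15 of 26 up and 3 down (17 and 3 adjusted over the list alone), led by RGS1 (7.37 ± 0.30) and the phosphatase gene DUSP1 (5.07 ± 0.21), while SOCS3 was lower (-2.91 ± 0.51). The immediate early list had an adjusted p of 1.15e-05 by camera, and adjusted p = 0.0297 with an estimated correlation. Of 19 complement and phagocytosis genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone), with complement C3 up by 8.12 ± 0.41 and C1QB by 2.21 ± 0.26. By camera, the complement list had an adjusted p of 0.00293, but adjusted p = 0.477 with an estimated correlation. Interferon response genes fell in 20 of 27 cases and rose in 1 (21 and 1 adjusted over the list alone), with ISG15 at -2.55 ± 0.22 and the chemokine gene CXCL10 at 2.98 ± 0.54. For the interferon list, camera gave an adjusted p of 3.77e-05, but adjusted p = 0.452 with an estimated correlation. Of 20 Alzheimer risk genes expressed in microglia, 10 rose and 4 fell (11 and 4 adjusted over the list alone), among them the sorting receptor gene SORL1 at 7.32 ± 0.28 and BIN1 at 4.74 ± 0.19. The Alzheimer risk list had an adjusted p of 0.0319 by camera, but adjusted p = 0.388 with an estimated correlation and 0.0873 after quantile normalization. Of 6 measured pluripotency genes, 4 fell, also when adjusted over the list alone, among them LIN28A, an RNA-binding protein of stem cells, which was at least 105-fold lower. By camera, the pluripotency list had an adjusted p of 0.00701, but adjusted p = 0.0643 with an estimated correlation. Of 11 mural cell and fibroblast genes, 8 fell and none rose, also when adjusted over the list alone. For the mural cell list, camera gave an adjusted p of 3.77e-05, and adjusted p = 0.0232 with an estimated correlation.

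Other genes with the largest increases in this comparison were the secreted protease gene HTRA1 (ratio 16100, counting interval 11000 to 24700, with 25 of its 26 progenitor reads in 1 library), the sulfotransferase gene GAL3ST4 (7040, 4510 to 11700), the sialic acid receptor gene SIGLEC8 (2180, 1360 to 3740) and the double-stranded RNA sensor gene TLR3 (at least 476-fold). The largest decreases included the chemokine gene CCL13 (ratio of progenitor to transplanted 1320, counting interval 837 to 2230, with 14 of its 18 transplanted reads in 1 library), the cytochrome gene CYP1B1 (2320, 1330 to 4500) and the matrix glycoprotein gene THBS1 (2660, 1140 to 8200). CSF1R, the receptor targeted by PLX5622 (chromosome 5, 150053291 to 150113372), rose by 1.66 ± 0.40 (adjusted p = 0.00412), TREM2 by 2.66 ± 0.32, APOE by 3.18 ± 0.33 and SPP1 by 2.54 ± 0.47. CD14 fell by 2.04 ± 0.26, but the progenitors had been chosen as CD14+. MKI67, a proliferation marker, did not pass the test (-0.67 ± 0.97, adjusted p = 0.613). In total 2544 genes were higher and 3052 lower in transplanted cells out of 12268 tested, 1608 and 2157 of them by at least 2-fold. With the closest pair of libraries in each group averaged, which leaves fewer samples, the calls for CSF1R (1.45, adjusted p = 0.111) and SPP1 (2.58, adjusted p = 0.0516) were lost. Over all alternatives their adjusted p ran from 2.14e-08 to 0.111 and from 5.8e-16 to 0.0516. The call for CSF3R was lost without progenitor replicate 1 (adjusted p = 0.0571) or 2 (0.0654) and with averaged pairs (0.67, adjusted p = 0.225), in a range from 2.92e-07.

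**Figure D1:**
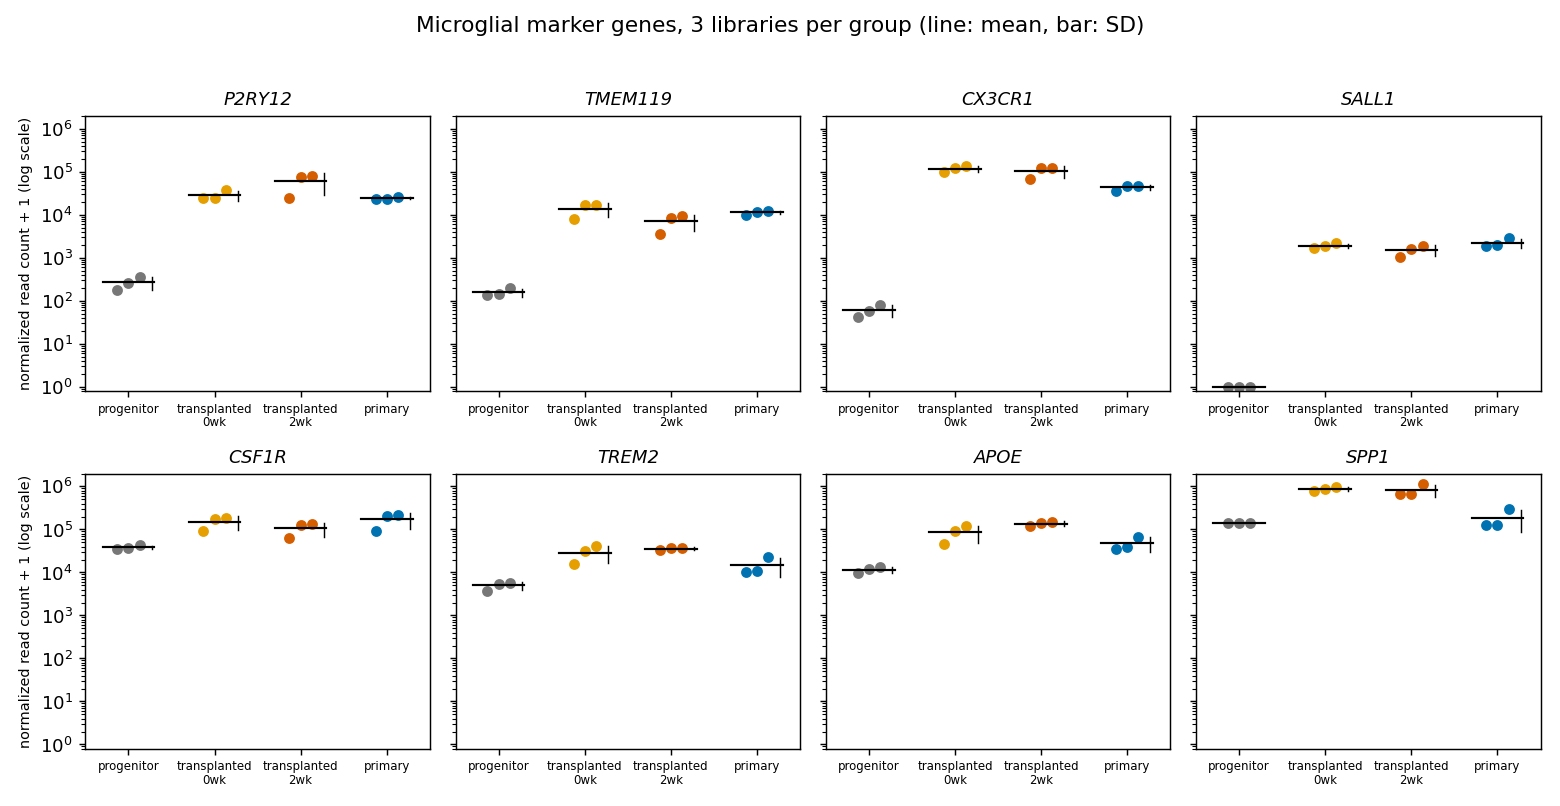
Normalized read count + 1 (log axis) of 8 marker genes in the 12 libraries, with 1 point per library, a line at the group mean and a bar of 1 SD. CX3CR1 averaged 58.7 in progenitors, 111500 over the transplanted libraries and 43325 in primary libraries, and SPP1 averaged 144000, 851370 and 184530 in the same order.

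The second question was how far transplanted cells differed from microglia of the human brain. Of the 26 measured immediate early and dissociation genes, 25 were lower in transplanted cells and none was higher, also when adjusted over the list alone, with a median of -2.94. The immediate early list had an adjusted p of 1.39e-14 by camera, and adjusted p = 0.00373 with an estimated correlation. NR4A1, an early-response nuclear receptor, was at 504 ± 443 normalized reads (n = 6) against 10066 ± 3510 (n = 3), a log2 fold change of -5.02 ± 0.22. HSPA1A, a heat shock chaperone, had a ratio of primary to transplanted of 8070 (counting interval 2230 to 66600), a value that is uncertain because its near-identical copy HSPA1B can share its reads. For several microglial markers no difference was called. This does not show that they were equal, since only 46.3% of simulated 2-fold changes were recovered in this comparison. P2RY12 differed by 0.69 ± 0.35 (adjusted p = 0.109), TMEM119 by -0.28 ± 0.31 (adjusted p = 0.452), SALL1 by -0.40 ± 0.23 (adjusted p = 0.16) and CSF1R by -0.40 ± 0.40 (adjusted p = 0.404), none past the test. TMEM119 was at 0.22 when the 0wk group alone was compared. CD14 (0.13 ± 0.26, adjusted p = 0.683) did not pass either, and was at -0.52 when the 2wk group alone was compared.

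CX3CR1 was higher in transplanted cells by 1.34 ± 0.25 (adjusted p = 0.000563), and SPP1 by 2.30 ± 0.47 (adjusted p = 0.00122). The lipid-binding genes APOE and TREM2 were higher by 1.17 ± 0.33 and 1.17 ± 0.32. Among 24 disease-associated microglia genes, 15 were higher and 3 lower (16 and 3 adjusted over the list alone), with a median of 1.44, or 1.29 with genes at 0 set to their bound. By camera, the disease-associated list had an adjusted p of 0.00287, but adjusted p = 0.205 with an estimated correlation. FABP5, a fatty acid carrier, was higher by 3.13 ± 0.17 and LIPA, lysosomal acid lipase, by 2.09 ± 0.16, whereas CST7, a cysteine protease inhibitor, was at least 63.2-fold lower and the integrin gene ITGAX differed by -0.97 ± 0.16. Of 27 lysosome genes, 16 were higher and 1 lower (16 and 1 adjusted over the list alone), including the protease gene CTSD at 2.27 ± 0.28. For the lysosome list, camera gave an adjusted p of 0.000778, but adjusted p = 0.445 with an estimated correlation. Of 23 homeostatic genes, 5 were higher and 7 lower (5 and 7 adjusted over the list alone), with the sugar transporter gene SLC2A5 at -4.07 ± 0.23, SYNDIG1 at -2.39 ± 0.22 and ENTPD1, an ATP-degrading enzyme, at 1.39 ± 0.22 (camera, adjusted p = 0.692).

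Genes of border-associated macrophages were higher in 10 of 16 cases and lower in 2 (10 and 2 adjusted over the list alone), led by the hyaluronan receptor gene LYVE1 (3.17 ± 0.21) and the scavenger receptor gene COLEC12 (3.5 ± 0.33). The border-associated list had an adjusted p of 0.00457 by camera, but adjusted p = 0.187 with an estimated correlation. Interferon response genes were lower in 21 of 27 cases and higher in none, also when adjusted over the list alone, with IFI44L at -5.63 ± 0.41 and XAF1 at -3.43 ± 0.31. By camera, the interferon list had an adjusted p of 5.72e-06, but adjusted p = 0.422 with an estimated correlation. Of 25 cytokine and NF-kB target genes, 13 were lower and 3 higher (13 and 3 adjusted over the list alone), including the inhibitor gene NFKBIA (-3.47 ± 0.18) and the chemokine genes CXCL8 (-3.92 ± 0.25) and CCL2 (2.86 ± 0.45, or 3.63 without primary replicate 1). For the NF-kB list, camera gave an adjusted p of 0.00266, but adjusted p = 0.38 with an estimated correlation. Cell cycle genes were higher in 16 of 34 cases and lower in none, also when adjusted over the list alone, among them the replication helicase genes MCM5 (1.88 ± 0.18) and MCM3 (1.94 ± 0.19). The cell cycle list had an adjusted p of 1.98e-06 by camera, but adjusted p = 0.501 with an estimated correlation. Ribosomal protein genes were higher in 22 of 32 cases and lower in none (25 and 0 adjusted over the list alone), with RPLP0 at 1.73 ± 0.30. This pools unlike groups: their transcripts took 1.21% of the normalized reads in 0wk and 2.89% in 2wk libraries. In primary libraries they took 1.31% (0.73% to 2.45%). By camera, the ribosomal protein list had an adjusted p of 2.05e-05, but adjusted p = 0.59 with an estimated correlation. MKI67 was at 1.35 ± 0.97 (adjusted p = 0.254) and at -0.50 without primary replicate 1.

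Markers of other cells were compared as well, although the transplanted cells came from the stem cell line H1 and were taken from mouse brain. Other human cells could therefore reach mainly the primary libraries, so lower values in transplanted cells partly follow from the design. Of 15 T and NK cell genes, 13 were lower in transplanted cells and 1 higher (13 and 1 adjusted over the list alone), among them CD8A, a coreceptor of cytotoxic T cells, which was at 61.0 ± 6.55 normalized reads in primary libraries and not detected in transplanted ones. By camera, the T and NK cell list had an adjusted p of 9.82e-06, but adjusted p = 0.173 with an estimated correlation. All 6 measured neutrophil and mast cell genes were lower, also when adjusted over the list alone, including the chemokine receptor gene CXCR1 at 1098 ± 35.1 in primary libraries and 0.635 ± 0.723 in transplanted ones. For the neutrophil and mast cell list, camera gave an adjusted p of 0.000211, and adjusted p = 0.0451 with an estimated correlation. Astrocyte genes were lower in 8 of 10 cases and higher in 1 (8 and 1 adjusted over the list alone). The astrocyte list had an adjusted p of 0.0079 by camera, but adjusted p = 0.173 with an estimated correlation. Of 10 endothelial genes, 8 were lower and 2 higher (8 and 2 adjusted over the list alone), among them the tight junction gene CLDN5 at a ratio of primary to transplanted of 280 (counting interval 175 to 480). By camera, the endothelial list had an adjusted p of 0.0331, but adjusted p = 0.173 with an estimated correlation and 0.0798 after removal of GC and length trends.

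The largest single differences also included genes outside these lists. RETN, which encodes resistin, was higher in transplanted cells at a ratio of 487 (counting interval 237 to 1210; log2 fold change 8.65, or 7.85 to 9.30 without 1 library), the growth factor carrier gene IGFBP4 by 7.92 ± 0.27 log2 units and the transcription factor gene MYBL2 by 6.37 ± 1.16 (4.07 without primary replicate 1, 7.49 without 2 and 7.56 without 3). The ubiquitin ligase gene TRIM4 was not detected in transplanted cells, at least 320-fold lower, and the mitochondrial protein gene CHCHD2 had a ratio of primary to transplanted of 1630 (counting interval 635 to 5970, with all 4 transplanted reads in 1 library). In total 3236 genes were higher and 3732 lower in transplanted cells, 1968 and 2753 of them by at least 2-fold. With the closest pair of libraries in each group averaged, the calls for TREM2 (0.87, adjusted p = 0.153), APOE (0.91, adjusted p = 0.178) and SPP1 (2.15, adjusted p = 0.0774) were lost, and that for APOE also after removal of GC and length trends (0.38, adjusted p = 0.0568) and with the 0wk group alone (0.78, adjusted p = 0.0948). The lowest adjusted p over all alternatives was 1.12e-07 for TREM2, 2.8e-07 for APOE and 7.01e-12 for SPP1.

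**Figure D2:**
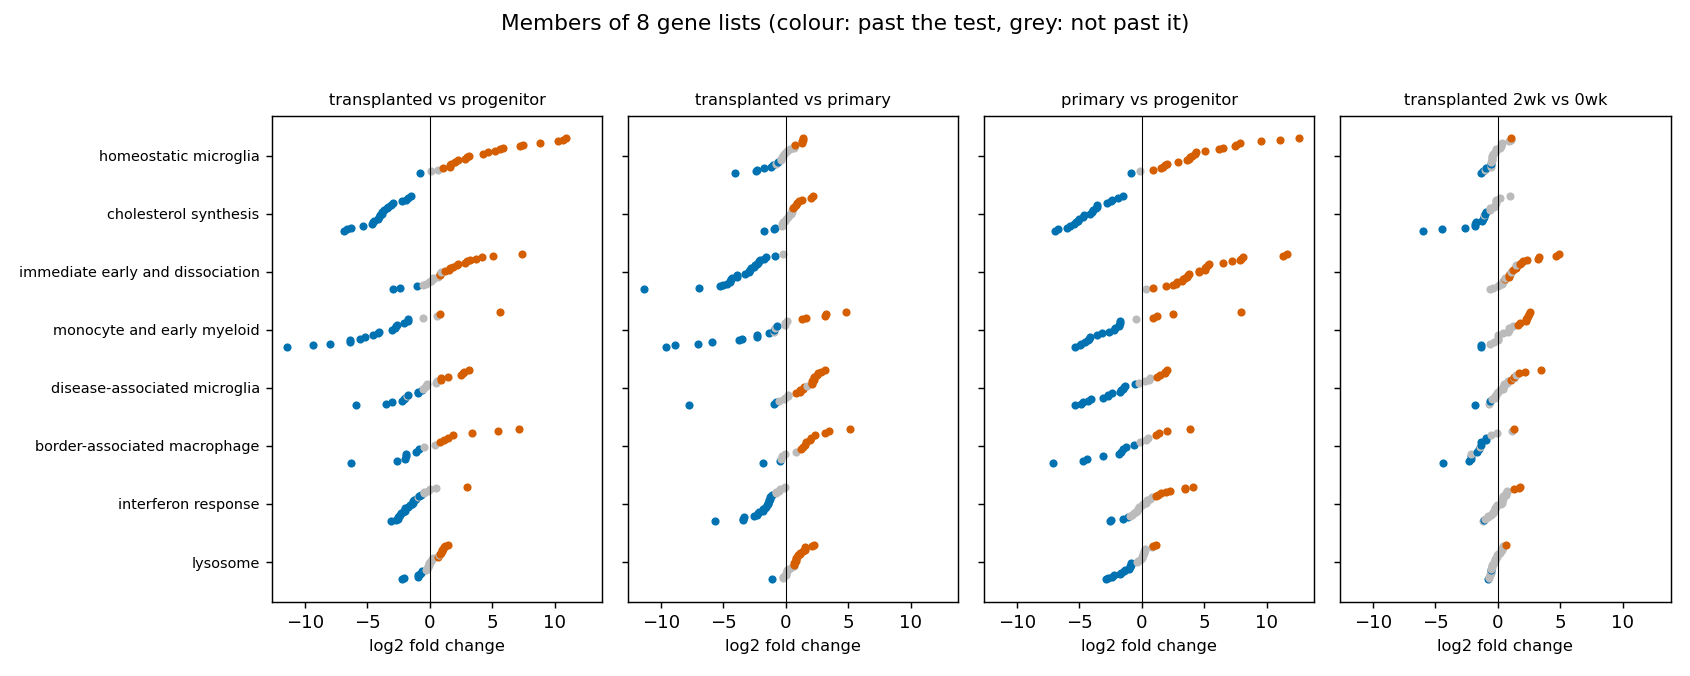
Log2 fold change of each measured member of 8 gene lists in the 4 comparisons, with 1 point per gene, coloured where the gene passed limma's test at an adjusted p of 0.05 and grey where it did not. All 21 cholesterol synthesis genes lie below 0 against progenitors, and 25 of 26 immediate early genes are lower in transplanted than in primary cells.

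The third question was what set primary microglia apart from the progenitors. Microglial genes were higher in primary cells: SALL1 was at least 1230-fold and SYNDIG1 at least 3520-fold higher, CX3CR1 was at 9.54 ± 0.28, P2RY12 at 6.55 ± 0.40 and TMEM119 at 6.18 ± 0.35. Of 23 homeostatic genes, 21 were higher and 1 lower (21 and 1 adjusted over the list alone), with a median of 4.04. For the homeostatic list, camera gave an adjusted p of 3.49e-12, but adjusted p = 0.0578 with an estimated correlation. All 21 cholesterol synthesis genes were lower, also when adjusted over the list alone, with a median of -4.15, INSIG1 at -6.01 ± 0.21 and MSMO1, a sterol demethylase, at -5.30 ± 0.20. The cholesterol synthesis list had an adjusted p of 1.85e-15 by camera, and adjusted p = 0.0033 with an estimated correlation. Immediate early and dissociation genes were higher in 25 of 26 cases, also when adjusted over the list alone, with a median of 4.57, RGS1 at 11.30 ± 0.35 and DUSP1 at 7.87 ± 0.25. By camera, the immediate early list had an adjusted p of 2.62e-17, and adjusted p = 0.00203 with an estimated correlation.

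Transcription factor genes of microglia and myeloid cells were higher in 14 of 17 cases and lower in 1 (14 and 1 adjusted over the list alone), with BHLHE41 at 3.79 ± 0.24 and SPI1, which encodes PU.1, at -1.44 ± 0.27. For the transcription factor list, camera gave an adjusted p of 0.000223, but adjusted p = 0.118 with an estimated correlation. Monocyte and early myeloid genes were lower in 16 of 21 cases and higher in 4 (16 and 4 adjusted over the list alone), including LGALS1, a galectin gene, at -4.89 ± 0.35 and the alarmin gene S100A12 at 2.49 ± 0.39. The monocyte list had an adjusted p of 0.000922 by camera, but adjusted p = 0.165 with an estimated correlation. All 6 neutrophil and mast cell genes were higher in primary libraries, also when adjusted over the list alone, among them CXCR2 at 5.15 ± 0.23. By camera, the neutrophil and mast cell list had an adjusted p of 7.11e-05, and adjusted p = 0.019 with an estimated correlation. T and NK cell genes were higher in 12 of 15 cases and lower in 2 (12 and 3 adjusted over the list alone). For the T and NK cell list, camera gave an adjusted p of 0.00328, but adjusted p = 0.355 with an estimated correlation. IGF2BP1, a fetal RNA-binding protein, was at 1399 ± 26.4 in progenitors and not detected in primary libraries, at least 374-fold lower, and IGF2BP2 had a ratio of progenitor to primary of 1350 (counting interval 527 to 4950). CSF1R was higher by 2.06 ± 0.46, TREM2 by 1.49 ± 0.37 and APOE by 2.00 ± 0.38. SPP1 (0.24 ± 0.55, adjusted p = 0.734) and MKI67 (-2.01 ± 1.12, adjusted p = 0.147, or -0.16 without primary replicate 1 and -2.97 without primary replicate 3, where its adjusted p was 0.0499) did not pass the test, and CD14, on which the progenitors had been chosen, was at -2.18 ± 0.30. In total 3274 genes were higher and 3422 lower in primary microglia, 2585 and 2559 of them by at least 2-fold, and the call for CSF1R was lost with the closest pair of libraries in each group averaged (1.82, adjusted p = 0.0719, in a range over alternatives from 1.77e-10).

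The comparisons with progenitors were then set side by side. Of the 2585 genes at least 2-fold higher in primary microglia, 1240 (48.0%) were also higher in transplanted cells, 195 were lower and 1150 did not pass the test. Of the 2559 at least 2-fold lower, 1467 (57.3%) were also lower, 96 were higher and 996 did not pass. The median log2 fold changes over these genes were 2.15 in primary and 0.72 in transplanted cells for the first set, and -1.93 and -0.94 for the second. Without a minimum fold, 1508 genes were higher in both comparisons and 1712 lower in both, where independent lists would share 679 and 851. A further 168 were higher in transplanted but lower in primary cells and 253 the reverse. Simulated unchanged groups shared at most 0 and 0, but they had almost no called genes to share (means of 0.05 and 0.1 higher, 0 lower). They therefore set no reference for this overlap. Pearson's r of the fold changes across the 12268 genes was 0.639 and Spearman's rho 0.515, against 0.579 and 0.542 for simulated unchanged groups that share the progenitor libraries. The covariance was 2.5 against a simulated 0.102, a covariance difference of 2.39. The simulated groups held no effects, so this difference does not tell shared changes from effects of the progenitors, which both comparisons use. Genes are not independent replicates, and part of the excess over independent lists may come from the shared progenitors, whose 3 libraries were not divided between the comparisons.

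Over all genes tested, the transplanted libraries lay 199 to 219 units from the mean primary profile (206 ± 8.16, n = 6), progenitors 237 to 241 (239 ± 2.08, n = 3) and primary libraries 96.7 ± 30.4 from the others of their group. The difference between transplanted and progenitor distances was -32.6 (exact two-sided permutation test, p = 0.0119, the smallest that 84 splits can give). With the closest pair in each group averaged it was -31.7 and no longer passed (exact p = 0.0667, with fewer samples). By rank, transplanted libraries correlated across genes with primary libraries at a Spearman's rho of 0.779 to 0.858 and with progenitors at 0.822 to 0.873, while primary and progenitor libraries correlated at 0.743 to 0.762. The first 3 principal components held 41.4%, 35.1% and 7.92% of the variance, and the first separated progenitors and the second transplanted from primary libraries. On the third the 0wk libraries lay at 38.3 to 55.1 and the 2wk libraries at -61.2 to -33.8, but the primary libraries also spread, from -34.3 to 22.5.

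The last comparison was between the transplanted groups. In 2wk cells the cytoskeletal gene LSP1 (chromosome 11, 1852970 to 1892267) was at 3133 ± 1470 normalized reads against 27.3 ± 11.2 in 0wk cells (n = 3 each), a log2 fold change of 6.77 ± 0.34 (adjusted p = 6.49e-07). The surface glycoprotein gene CD52 was higher by 5.32 ± 0.45. The scavenger receptor gene MARCO was lower (-4.90 ± 0.85, or -3.50 without 2wk replicate 1 and -5.72 without 2wk replicate 4), as was the semaphorin gene SEMA6A (-4.75 ± 0.48). Of 21 cholesterol synthesis genes, 11 were lower in 2wk cells and none higher (14 and 1 adjusted over the list alone), with a median of -0.98. The cholesterol synthesis list had an adjusted p of 2.49e-07 by camera, and adjusted p = 0.0407 with an estimated correlation. Immediate early and dissociation genes were higher in 2wk cells in 15 of 26 cases and lower in none (18 and 1 adjusted over the list alone), with a median of 1.08, led by the nuclear receptor genes NR4A2 (4.87 ± 0.28) and NR4A1 (3.20 ± 0.26). By camera, the immediate early list had an adjusted p of 5.04e-10, and adjusted p = 0.0134 with an estimated correlation.

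Of 16 border-associated macrophage genes, 10 were lower in 2wk cells and 1 higher (11 and 1 adjusted over the list alone), with a median of -1.39. For the border-associated list, camera gave an adjusted p of 0.000117, but adjusted p = 0.137 with an estimated correlation. LYVE1 was at 6458 ± 455 against 32879 ± 8510 and the lectin receptor gene CD209 at 49.5 ± 25.5 against 958 ± 268. Of 21 monocyte and early myeloid genes, 8 were higher and 2 lower (8 and 2 adjusted over the list alone), led by S100A4 (2.59 ± 0.29) and LGALS1 (2.51 ± 0.35). The monocyte list had an adjusted p of 0.00391 by camera, but adjusted p = 0.454 with an estimated correlation. The list's median was 0.87, but 0.0028 with genes at 0 set to their bound. Among 34 cell cycle genes, 10 were lower and 1 higher (10 and 1 adjusted over the list alone), with MCM3 at -2.10 ± 0.22 and MCM7 at -2.05 ± 0.28. By camera, the cell cycle list had an adjusted p of 0.0113, but adjusted p = 0.931 with an estimated correlation and 0.49 with fry, which asks whether the genes move on balance one way. Of 32 ribosomal protein genes, 11 were higher and none lower (22 and 0 adjusted over the list alone), including RPL7 at 1.78 ± 0.36. For the ribosomal protein list, camera gave an adjusted p of 7.49e-09, but adjusted p = 0.748 with an estimated correlation and 0.129 with fry.

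Of the microglial markers, P2RY12 (0.92 ± 0.40, adjusted p = 0.133), TMEM119 (-1.01 ± 0.35, adjusted p = 0.0662), CX3CR1 (-0.23 ± 0.28, adjusted p = 0.618), SALL1 (-0.36 ± 0.27, adjusted p = 0.391) and CSF1R (-0.52 ± 0.46, adjusted p = 0.467) did not pass the test between the groups. Neither did TREM2 (0.40 ± 0.37, adjusted p = 0.482), APOE (0.78 ± 0.38, adjusted p = 0.169), SPP1 (-0.13 ± 0.55, adjusted p = 0.907) or MKI67 (-1.20 ± 1.12, adjusted p = 0.499, and -1.86 without 2wk replicate 4). CD14 was lower in 2wk cells (-1.31 ± 0.30, adjusted p = 0.0116), a call that was lost under 6 of 26 alternatives. These were the fits without 0wk replicate 3 (adjusted p = 0.0529), 2wk replicate 1 (0.0591) or 2wk replicate 2 (0.0596), with only these groups (0.0857), with edgeR on recovered reads (0.0555) and with averaged pairs (-1.02, adjusted p = 0.298). In total 1010 genes were higher and 1178 lower in 2wk cells, 752 and 764 of them by at least 2-fold. A fit of these 6 libraries alone called 604 and 718 genes, edgeR on recovered reads 466 and 643, the fit without 2wk replicate 2 called 493 and 672, and 71 and 57 were called with the closest pair of libraries in each group averaged, where 45 of 59 list members named by the rule lost their calls, MCM7 and RPL7 among them.

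**Figure D3:**
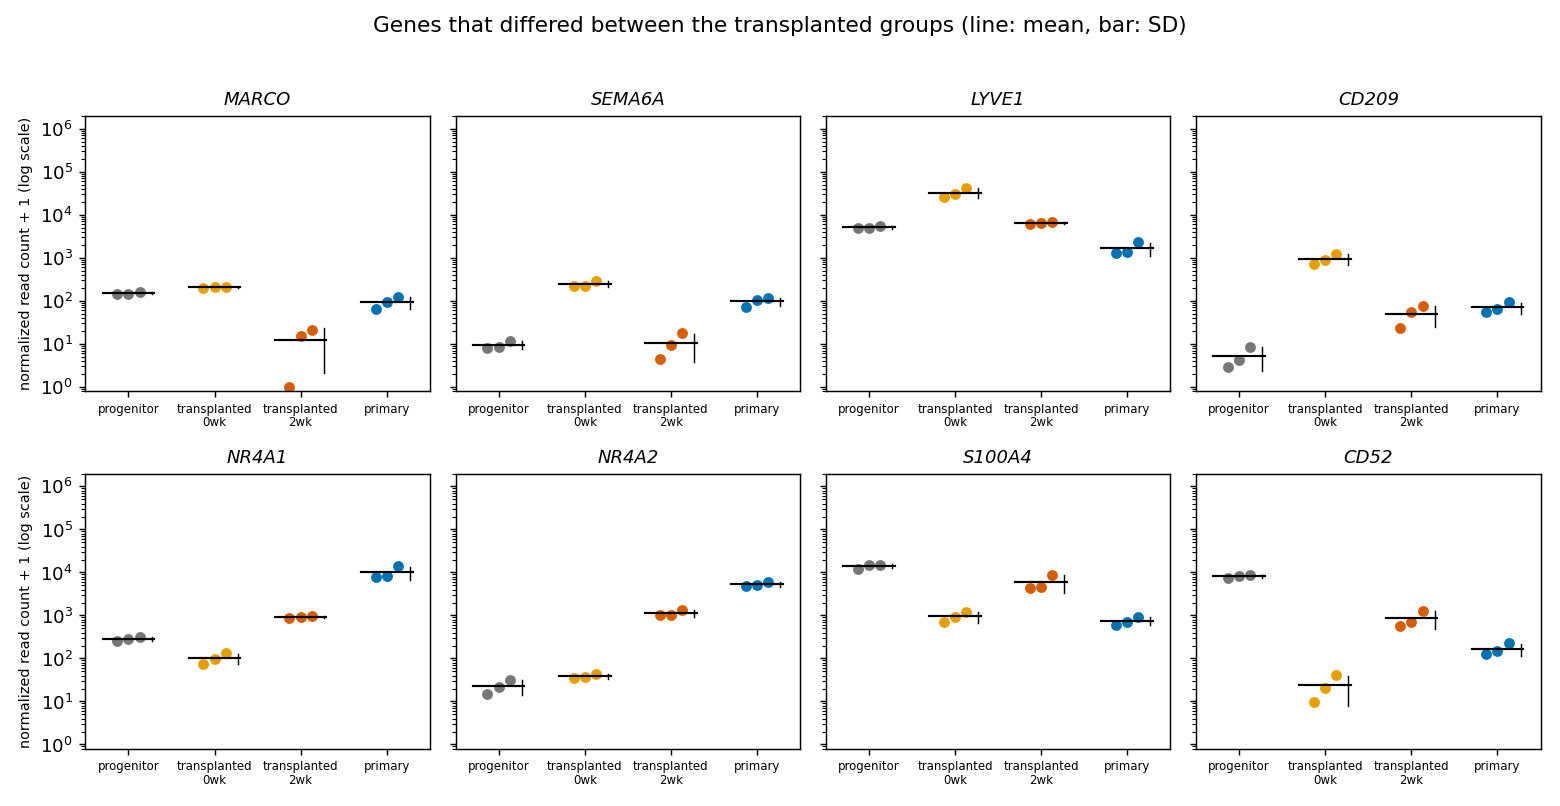
Normalized read count + 1 (log axis) of 8 genes that differed between the transplanted groups, with 1 point per library, a line at the group mean and a bar of 1 SD. SEMA6A averaged 244 in 0wk and 9.47 in 2wk libraries, and NR4A2 averaged 37.2 and 1122.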

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

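The counts over other splits of the libraries and the fits without each library were planned before the data were examined. The fits with averaged pairs, the removal of GC and length trends, and the tests of the other patterns weighed were chosen after the results had been seen. Against progenitors, 40 genes were higher in one transplanted group and lower in the other, each past limma's test in both groups and in the test of the difference between the groups. The nuclear receptor gene NR4A1 was at -1.52 ± 0.26 in 0wk cells and 1.68 ± 0.26 in 2wk cells, and the transcription factor gene CEBPD at -1.41 ± 0.33 and 1.28 ± 0.33. Against primary microglia, 49 genes did so. LSP1 was at -5.27 ± 0.34 in 0wk and 1.51 ± 0.34 in 2wk cells, CD52 at -3.0 ± 0.45 and 2.32 ± 0.45, and the intermediate filament gene VIM at -1.03 ± 0.34 and 2.33 ± 0.34. NR4A1, CEBPD and VIM were chosen for this paragraph after their values were seen.

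In 2-group fits over every split of the same libraries, the real split gave the highest count in each comparison. Transplanted against progenitor libraries gave 4695 changed genes, and the highest of the other splits 1876 (1 of 84 splits as large, a share under 0.05). Transplanted against primary libraries gave 5193 and at most 825 (1 of 84, also under 0.05). Each is the smallest share that 84 splits can give, and such splits treat the libraries as exchangeable. Because every group held 1 far closer pair, these counts do not exclude chance or libraries of a group made together. Primary against progenitor libraries gave 6943 and at most 0 in the others, and 2wk against 0wk libraries 1322 and at most 1, each 1 of 10, which are too few splits for a share under 0.05.

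The first pattern weighed is the difference between the transplanted groups. The 0wk libraries differed in how expression followed GC content (Spearman's rho across genes of -0.31 in replicate 1 against 0.48 and 0.41), but removing the GC and length trends of each library left 2812 changed genes against 2188, which argues against these trends as the whole source. Leaving out any 1 transplanted library left 1165 to 2849 changed genes, the lowest counts without a library of a closest pair and the highest with only a closest pair left in 1 group, so the part of 1 library stays open. Libraries of a group made or sequenced together could also give such a difference. With the closest pair in each group averaged as 1 sample, 128 genes were called, but that fit also held fewer samples. Because the labels give no batch, libraries made together cannot be told apart from the condition behind 0wk and 2wk.

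The second pattern is that immediate early and dissociation genes were highest in primary libraries. Neutrophils or monocytes among the sorted cells would bring their abundant S100A8 and S100A9. These together came to 3.44% of FOS in primary libraries, where FOS averaged 437909 normalized reads. That ratio covers FOS alone, the most abundant transcript there, and how much FOS such cells hold was not measured. Another member, HSPA1A, was at 3159 in primary libraries, below S100A9 at 9549. All 6 measured neutrophil and mast cell genes were also higher in primary than in transplanted cells, so these cells stay open as a source. After removal of GC and length trends, 25 members were still lower in transplanted cells, with a median of -3.18. Handling of the tissue before the sort could account for the median of -2.94, and cannot be told apart from a difference between the cells, because source and handling go together in this design.

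The third pattern is a set of 40 genes at 3 or fewer reads in every transplanted library and at 100 or more in every primary library, with TRIM4 and FCN1 among them. Over these genes the median log2 ratio of progenitor to primary was -4.93, below the lowest of 10000 random sets drawn from genes at 100 or more in every primary library (-0.93), although FCN1 stood higher in progenitors (2737) than in primary libraries (789). This does not decide whether reads that also match the mouse genome were lost, since progenitors can lack a gene for other reasons and the labels do not say whether they were spared. Blood cells in the primary libraries may account for some, since 3 of the 40 are on the lists of blood cells. Those lists hold few markers, so more of the 40 could come from such cells, and the count sets no upper limit. A difference between the stem cell line and the donors may also account for some. Of the 40, 13 were also at 3 or fewer reads in every progenitor library, TRIM4, ZBTB16 and HSPA1A among them. CXCR1, which is on the lists of blood cells, was also among these 13, so absence from progenitors does not single out the line. All of these explanations stay open, because line, source and tissue go together.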

How the results depend on the processing

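Averaging the closest pairs and removing GC and length trends were chosen after seeing the data, and the other alternatives before. Apart from the markers, the named genes had been picked for large changes or a low adjusted p, which favours kept calls. Over the named genes, 11040 of 11549 values under alternatives kept direction and side of the threshold, 475 lost the call, 18 gained one and 16 reversed. Over the 50 list results called, 293 of 350 values did and 57 lost the call. With an estimated correlation, 38 of the 50 lost it. The call was lost for 8 after GC and length removal, 5 with fry, 4 after quantile normalization and 2 with averaged pairs. All 20 genes named for their size in each comparison with primary or progenitor libraries kept their calls without any 1 library and with averaged pairs, while between the transplanted groups RIBC2 lost its call in both and with edgeR, and TMIGD2 with averaged pairs. Of the list members named and called, some lost the call without 1 library: 5 of 89 against progenitors, 8 of 88 against primary, 6 of 92 for primary against progenitor and 24 of 59 for 2wk against 0wk. Counts for 2wk against 0wk (1010 higher and 1178 lower) became 604 and 718 with only the groups compared, 2019 and 2228 with array quality weights, 360 and 456 at an adjusted p under 0.01, 466 and 643 with edgeR and 71 and 57 with the closest pair of each group averaged; the cause was not tested. Array quality weights (0.105 to 19.9, from a fit that stopped before its tolerance) also gave 4042 higher and 4817 lower genes for transplanted against progenitor and 5047 higher for primary against progenitor. With averaged pairs these comparisons gave 1418 and 1808, 1840 and 2422 (transplanted against primary) and 2142 and 2079, the distance difference was -31.7 (exact two-sided permutation p = 0.0667, with fewer samples), and 856 and 979 genes changed the same way in both comparisons. Leaving out each library gave, for 2wk against 0wk, 493 to 1566 higher and 613 to 1790 lower. The count fell by over 1.5 times without 0wk replicate 3 (558 and 613), 2wk replicate 1 (504 and 677) or 2wk replicate 2 (493 and 672) and rose without primary replicate 1 (1566 and 1790), which shares the estimate of the spread. The other ranges were 1987 to 2980 and 2349 to 3491 (transplanted against progenitor), 2737 to 3490 and 3188 to 4064 (transplanted against primary), 2798 to 3607 and 2861 to 3746 (primary against progenitor), -37.6 to -28.9 (distance difference), and 1192 to 1786 and 1326 to 2001 (the same way in both). Reversed values, none past the test in the fit as reported except MS4A7, MT-ND4L and TYROBP, were these, with the cause not tested. For transplanted against primary they were MKI67 at -0.63 with array weights and -0.50 without primary replicate 1, with up to 2.31 without primary replicate 3 (1.35 as reported), CD14 at -0.022 with the replicate block, -0.033 without 2wk replicate 4 (up to 0.256 without 0wk replicate 1), -0.52 with 2wk alone and -0.28 after GC and length removal (0.13), TMEM119 at 0.22 with 0wk alone (-0.28), MS4A7 at 0.17 with 2wk alone (-0.49) and MT-ND4L at -0.49 after GC and length removal (0.74), the only reversed value that itself passed the test (adjusted p = 0.0253). For primary against progenitor they were SPP1 at -0.14 with array weights and -0.17 without primary replicate 1, with up to 0.45 without primary replicate 2 (0.24) and TYROBP at 0.086 after GC and length removal (-1.43). For 2wk against 0wk they were CX3CR1 at 0.076 with the replicate block and 0.042 without 2wk replicate 4, with down to -0.37 without 2wk replicate 1 (-0.23), and SPP1 at 0.001 with edgeR and 0.023 with averaged pairs (-0.13). Same-numbered libraries did not deviate together (2 of 15 pairs had a correlation over 0.1, range -0.23 to 0.15), and the replicate block called 552 and 700 genes for 2wk against 0wk. Quantile normalization moved the median of all genes from -0.07 to 0.03 against progenitors and from -0.09 to 0.05 against primary, and the share of higher genes among those called from 45.5% to 52.0% and from 46.4% to 52.1%. DESeq2 on recovered reads called 808 and 1091 genes for 2wk against 0wk. Depth limits mainly the genes near 0, for which only bounds or counting intervals are given.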

Other observations

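The genes of the first paragraph were picked by a limit set after the data had been seen, which was itself not tested. At 3 or fewer reads in every primary library and at least 30 normalized reads in every transplanted library stood 6 genes: CALB2, HOXB7, IGF2BP1, IGF2BP2, PCDHB2 and SLC38A4. IGF2BP1 and IGF2BP2 encode RNA-binding proteins of fetal tissue. IGF2BP1 was at 1399 ± 26.4 normalized reads in progenitors (SD, n = 3) and 63.5 ± 25.5 in transplanted cells (n = 6), with 0 reads in primary libraries. IGF2BP2 was at 2085 ± 340, 208 ± 124 and 1.55 ± 0.271 in the same order, and LIN28B, which encodes another RNA-binding protein and was added after its values were seen, at 530 ± 61.8, 90.5 ± 28.6 and 3.56 ± 3.75. LIN28A, a related gene, was at 366 ± 26.7 in progenitors and at 0 in every transplanted and primary library. CALB2, which encodes a calcium-binding protein, was at 333 ± 181 in transplanted cells, 0.923 ± 1.6 in progenitors and 1.13 ± 1.26 in primary cells. SLC38A4, an amino acid transporter gene, was at 125 ± 72.8 in transplanted cells, with 0 reads in progenitors.

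Lipid genes outside the synthesis list gave a mixed picture between transplanted and primary cells: 10 of 13 efflux and LXR target genes were higher and 2 lower (10 and 2 adjusted over the list alone), with the desaturase gene SCD at 2.28 ± 0.26 and ACSL1, which activates fatty acids, at -1.97 ± 0.23 (camera, adjusted p = 0.015, but adjusted p = 0.168 with an estimated correlation). Glycolysis and hypoxia genes went both ways there, with 15 of 26 higher and 9 lower (15 and 9 adjusted over the list alone). PKM, pyruvate kinase, was at 2.48 ± 0.23 and ENO1, enolase, at 2.41 ± 0.22, while PFKFB3, which drives glycolytic flux, was at -3.58 ± 0.27 and the hypoxia-induced peptide gene ADM at -3.18 ± 0.33, and camera did not call the list (adjusted p = 0.108).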
